A study of Pimephales promelas and Coturnix japonica and Xenopus laevis with 724 samples.

How the data were processed

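The series holds RNA sequencing of liver (cormorant, quail and adult minnow) and of embryos (minnow, leopard frog, trout and clawed frog) after exposure to 1 of 8 chemicals or a control treatment. Per the labels' protocols, RNA was extracted with column kits and libraries were sequenced as paired-end reads on Illumina NovaSeq or HiSeq instruments. The authors deposited whole-number counts per s2f identifier, 1 table per species, life stage and chemical, 49 tables in all. The aligner or counter, its version and the reference behind the s2f identifiers are not given in the sources used here. The values are treated as raw counts because they are whole and because library totals differ, from 4066220 to 69838406. Identifiers were used as the files give them: 0 of 42403 matched the reference table of 64593 genes by any of its name columns. Gene lists fixed before the data were examined, gene set tests and marker genes of other cell types therefore had no members to test and were left out, and GC content, length and coordinates were not analysed here.

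Each library was placed in a group by its labels for species, stage, chemical and level. A column was used only where its name matched 1 sample; 52 columns of per-sample counts in 10 tables matched none and were not used here. They lie in the tables for which the labels name no control, and their names resemble those of labelled controls in other tables, but no sample carries them. A first search of the files for repeated columns, which took in every column, found each of them to hold the same set of counts above 0 as a labelled control of another table of the same species. Whether they are those controls is stated by no label, and no result rests on that search. In the early-life quail chlorpyrifos table, 2526 identifiers with an empty cell were left out. The level labels are used as given; where a level is a number the labels give no unit, and for some leopard frog, clawed frog and minnow tables the title and the level label name the level differently, in which case the level label was used.

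Pairs of libraries of a group were compared with a chi-square statistic over identifiers with an expected count of at least 5. The closest pair, controls 3 and 3.1 of the clawed frog lead table, gave 1.302 per degree of freedom, against 2.769 or more for every other pair. These 2 differed by little more than sampling noise and were summed into 1 library. That step departs from the planned fit, which held both, and was chosen after the counts had been seen; both ways are given among the alternatives. The 10 libraries of the early-life quail lead table held the same counts as those of the adult quail lead table, for all 18350 identifiers, and the early-life table, which has no labelled controls, is not among the experiments with controls.

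Each table was tested alone. All level groups of a table entered 1 fit (in the minnow ethinylestradiol and fluoxetine tables the numbered levels were fitted apart from MED, HIGH and the controls). Identifiers with low counts were removed with filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM factors, and the highest level was compared with the control, or with MED where the labels name no control, by edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3). In the numbered minnow embryo series the lowest level was the reference. There the comparison set in advance was the highest level for fluoxetine, but for ethinylestradiol it was level 4 and not the highest, level 10, which has 2 libraries and was tested in the same fit. An identifier was called at a Benjamini-Hochberg adjusted p below 0.05 within a comparison. Normalised counts are counts scaled by the library total and its TMM factor, as CPM, and the standard error of a log2 fold change is its size divided by the square root of the quasi-likelihood F. Adult and early-life quail were tested for a difference in the change with benzo[a]pyrene and with ethinylestradiol by an interaction term in 1 fit over both tables. That fit and its simulation took 1 estimate of the spread per identifier for both stages. Whether the spread differs between the stages was not tested. Adjusted p-values of edgeR, DESeq2 and the tests below are two-sided unless called one-sided.

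Lists of calls from 2 experiments were compared by identifier and direction with a one-sided Fisher's exact test, for every pair in which both lists held at least 10 identifiers, among identifiers tested in both; p-values were adjusted over all 14 overlaps within a chemical and 92 between chemicals. Recurrence of an identifier over experiments was tested against the Poisson-binomial distribution given by the share of calls in each experiment. The rule for naming, fixed in advance, allows at most 2 identifiers that rose and 2 that fell where no gene names can be had, and does not say which. Those called in the most experiments in a direction were taken, ties going to the larger mean absolute log2 fold change, and this way of choosing was set after the files had been seen.

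The edgeR test of each comparison, the interaction test and the Poisson-binomial test were tested on simulated data; the overlap test was not. For each of 51 comparisons, counts were drawn from the means and library sizes of its libraries, with 200 identifiers changed, and between 10874 and 17849 identifiers entered the fit. A median of 28.36% of 1.5-fold, 67.16% of 2-fold and 93.94% of 4-fold changes was called, and 4.849% of calls over all comparisons together were false. Single comparisons differed: 7 of 51 calls were false for ethinylestradiol in adult minnow and 21 of 167 in trout embryos. For fluoxetine in trout embryos 1 of 138 was false. The draws held no structure shared between libraries, so the false share does not cover one. For 2-fold changes the share called ran from 5.97% to 92.54% of the changed identifiers. Depth and the spread between libraries both enter these shares.

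Alternatives were RLE size factors, no low-count filter, DESeq2 (1.42.0), a fit of only the 2 groups compared, the replicate number or letter as a block, and leaving out each library in turn; 1.5 times was the bound for calling a count similar. Further ones were added after the counts had been seen: keeping both control libraries numbered 3 in the clawed frog lead table, leaving out each MED and control library in turn for trenbolone at MED in clawed frog and for ethinylestradiol at MED, all alternatives for the other numbered levels in minnow embryos, and the alternative fits of overlaps, of recurrence and of each lower level. Whether replicate numbers pair libraries was checked by correlating the deviations of same-numbered libraries from their group means. In 4 of 50 comparisons every pair was over 0.1, all in minnow embryos: chlorpyrifos (lowest 0.156), ethinylestradiol (0.304), fluoxetine (0.214) and lead (0.233). The labels do not say what the letters stand for. Other splits of the libraries were counted for each comparison, 40 per comparison including the real one, or all where fewer exist. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.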

Results

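Gene-level read counts from RNA sequencing were compared for 724 libraries of 6 vertebrate species, each exposed to some of 8 chemicals or kept as controls. The chemicals were benzo[a]pyrene (a polycyclic aromatic hydrocarbon formed in combustion), chlorpyrifos (an organophosphate insecticide), ethinylestradiol (a synthetic oestrogen), fluoxetine (a serotonin reuptake inhibitor), hexabromocyclododecane (a brominated flame retardant), lead, selenomethionine (an organic form of selenium) and trenbolone (a synthetic androgen). The libraries fell into 49 tables, each for 1 species, life stage and chemical, and 193 of them were labelled as controls. Liver was sequenced from double-crested cormorants at an early life stage (54 libraries), from adult fathead minnows (78), and from Japanese quail as adults (96) and at an early life stage (100). These numbers follow the labels, and 10 of the 100 early-life quail libraries held the same counts as 10 of the adult ones, so 724 is not a number of distinct libraries. Embryos were sequenced for fathead minnow (142 libraries), northern leopard frog (60), rainbow trout (73) and African clawed frog (121). A group of 1 table at 1 level held 5 libraries in most cases, and 2 to 7 in all. Levels are named as the labels give them, mostly MED and HIGH, and where the labels give numbers they carry no unit.

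Total counts ran from 4066220 to 69838406 per library, with a median of 15779699.5. The median total was lowest in leopard frog embryos, at 9658578.5, and highest in early-life quail, at 21330772.5. Counts were given per identifier with the prefix s2f, 42403 in all, and 16324 of them occurred in the tables of all 6 species. The files do not pair these identifiers with gene names, and 0 of the 42403 matched the reference table of 64593 genes, so results are given by identifier and by group of identifiers, and 2 identifiers that rose and 2 that fell are named. Nothing in the labels says whether libraries of a group came from separate animals or pools. The edgeR and DESeq2 p-values therefore measure the spread between these libraries, which may be technical. The overlap test takes identifiers as independent units, and the recurrence test takes calls of different experiments as independent. Neither measures a spread between libraries, and identifiers that change together would make the overlap p-values too small.

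The first question was which identifiers changed at the highest level of each chemical against the controls of the same table, in each species and life stage. Across 39 such experiments, 6820 calls were made, of which 4033 were higher and 2787 lower than in controls (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). At least 1 identifier was called in 19 experiments and at least 10 in 14. DESeq2 gave more than 1.5 times as many calls as edgeR, or calls where edgeR had none, for 48 of 62 counts. Benzo[a]pyrene gave 3506 calls over 8 experiments and lead 2488 over 3. Ethinylestradiol gave 391 over 7, selenomethionine 285 over 5 and hexabromocyclododecane 147 over 2. Chlorpyrifos gave 3 calls over 4 experiments, and fluoxetine and trenbolone gave none at the highest level in 6 and 4 experiments. African clawed frog embryos held 3589 of the calls and fathead minnow embryos 2642, while the 5 experiments in adult minnow liver held 24 and the 3 in adult quail liver 10. In simulated counts made from these libraries, a 2-fold change was recovered for a median of 23.88% of changed identifiers in the adult minnow comparisons, 44.03% in adult quail and 79.1% in clawed frog embryos, so the counts of calls of different species and stages rest on unequal sensitivity.

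**Figure D1:**
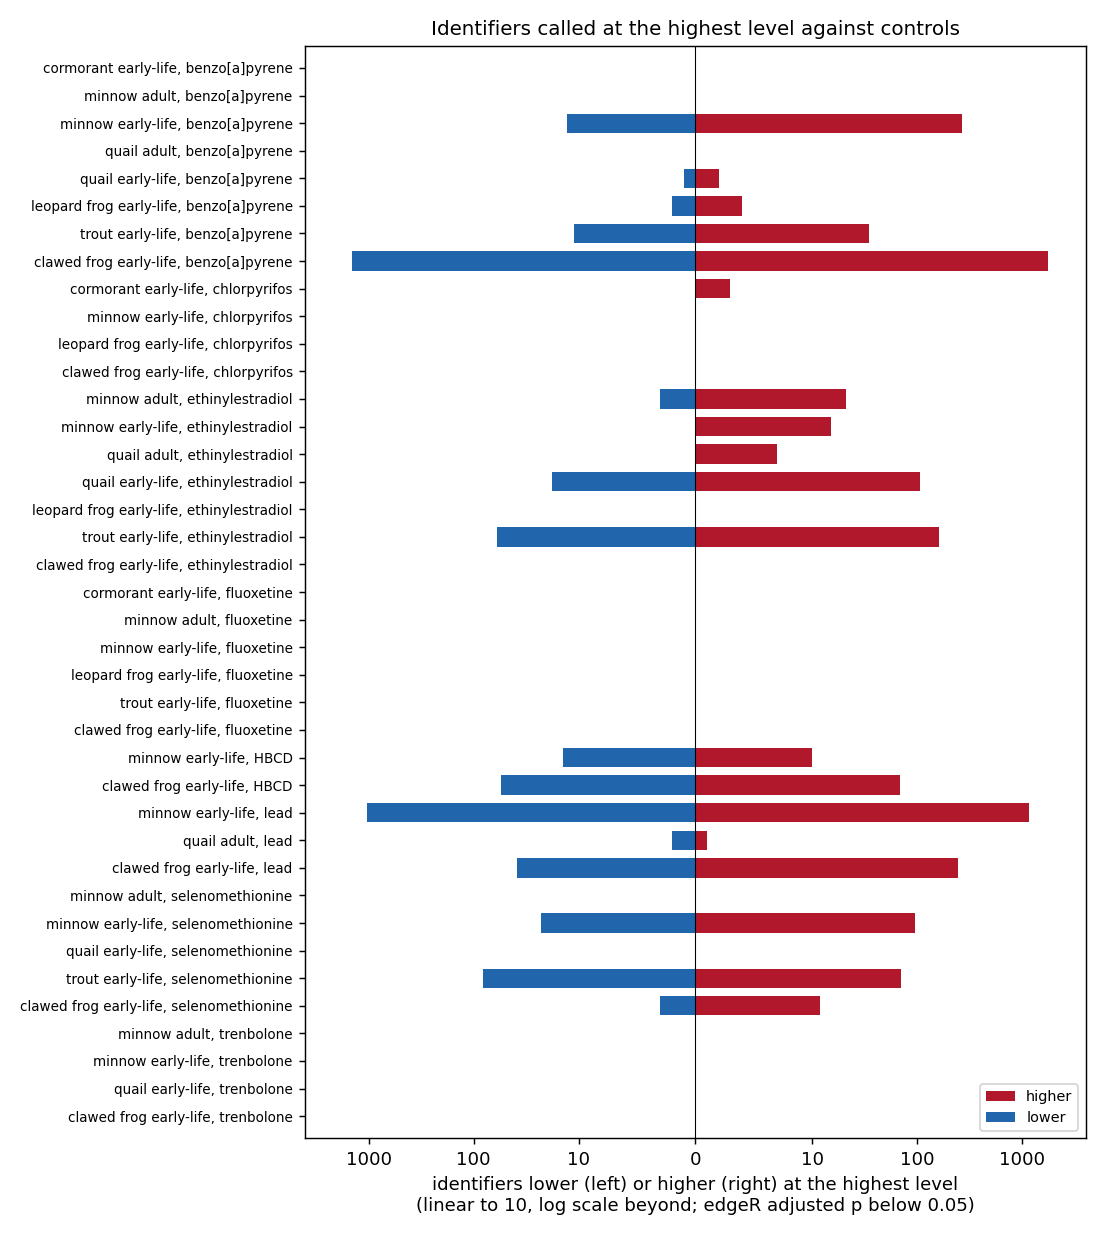
Number of identifiers higher (red, right) or lower (blue, left) at the highest exposure level than in the controls, for each of the 39 experiments with controls, grouped by chemical; the axis is linear to 10 and logarithmic beyond. The longest bars belong to benzo[a]pyrene in clawed frog embryos (1741 higher, 1428 lower) and lead in minnow embryos (1170 higher, 1033 lower), and no bar is drawn for fluoxetine or trenbolone.

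Benzo[a]pyrene changed 3169 of 15779 tested identifiers in clawed frog embryos (5 HIGH against 5 control libraries), 1741 upward with a median log2 fold change of 0.48 and 1428 downward with a median of -0.46. In fathead minnow embryos 269 identifiers rose (median 1.15) and 13 fell (median -0.81), again with 5 libraries in each group. In rainbow trout embryos, where 5 level numbers were tested against 7 controls, 35 rose (median 0.91) and 11 fell (median -0.60) at the level numbered 81 (n = 4). Lower levels in trout gave 0 calls at 1, 2 at 3, 12 at 9 and 64 at 27, and MED gave 185 calls in minnow embryos and 258 in clawed frog embryos. At level 1 in trout 1217 identifiers had an unadjusted p below 0.05, and DESeq2 also called 0. Leaving out HIGH replicate A raised the minnow count to 443, and the trout count fell to 30 without the level 81 replicate C, to 29 without D or E, and to 28 when only the 4 controls whose titles start with S were kept. In leopard frog embryos 4 rose and 2 fell, which dropped to 3 calls without HIGH replicate 2, 4 or 5 or control 2.

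In liver, benzo[a]pyrene gave at most 3 calls with edgeR at HIGH. Early-life quail had 2 identifiers higher and 1 lower (111 calls with DESeq2), a share of 66.67% higher that became 50% of 2 calls with RLE size factors, and 1 call was left without HIGH replicate 3 or 5. Early-life cormorant, adult minnow and adult quail gave 0 calls with edgeR, with 2055, 419 and 784 identifiers at an unadjusted p below 0.05. DESeq2 called 206, 0 and 1 in these experiments. Adult quail and early-life quail were also fitted together to test whether the change with benzo[a]pyrene differed between the stages: edgeR called 0 of 12996 identifiers, with 1111 at an unadjusted p below 0.05, and DESeq2 called 29.

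Identifiers that rose with benzo[a]pyrene were shared between minnow, trout and clawed frog embryos. Among the 11987 identifiers tested in minnow and clawed frog embryos, 117 rose in both, against 27.8 expected from independent lists (one-sided Fisher's exact test, adjusted p = 1.86e-46). Minnow and trout embryos shared 16 against 0.511 expected (adjusted p = 6.54e-20), and trout and clawed frog embryos 14 against 2.86 (adjusted p = 3.87e-07). Over all 8 benzo[a]pyrene experiments, 129 identifiers rose in at least 2, where independent calls give 24.5, and 10 rose in at least 3, where they give 0.0496. Of the identifiers that fell, 3 fell in at least 2 of the 8 experiments, where independent calls give 1.77. Minnow and trout embryos shared 0 of 12 and 10 that fell (0.00802 expected, Fisher's exact test, adjusted p = 1), and with so few expected a count of 0 does not show that falls are not shared. Controls were separate libraries in each experiment. The signs of the log2 fold changes did not agree in every pair of experiments, and these shares were not tested. Identifiers called in minnow embryos had the same sign for 80.6% of 227 in clawed frog embryos, 76% of 267 in trout embryos and 72.7% of 198 in cormorant liver, but for 49.4% of 253 in adult minnow liver, 47% of 183 in adult quail liver, 40.1% of 192 in early-life quail liver and 45.9% of 220 in leopard frog embryos. Those called in clawed frog embryos had the same sign for 66.7% of 2505 in minnow embryos and 43.1% of 2463 in trout embryos.

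Lead changed 2203 of 17479 tested identifiers in fathead minnow embryos, 1170 upward (median log2 fold change 0.50) and 1033 downward (median -0.37), with 5 libraries in each group. In clawed frog embryos 243 rose (median 0.61) and 39 fell (median -0.62). MED gave 49 calls in minnow, all higher, and 282 in clawed frog, 259 higher and 23 lower. Of 889 identifiers that rose in minnow embryos and 204 in clawed frog embryos among those tested in both, 90 were shared against 15.1 expected (Fisher's exact test, adjusted p = 2.05e-46). Of 713 and 26 that fell, 1 was shared against 1.55 expected (adjusted p = 1). None of the 4 overlaps of falling identifiers tested within a chemical passed the threshold. Outside lead the expected numbers were 0.00802, 0.0316 and 0.109, too small for a count of 0 to show that falls are not shared. Some overlaps of falls between different chemicals did pass and are given under other observations. Replicate letters paired the minnow libraries, and with the letter as a block the minnow count was 3854. The clawed frog count fell to 184 without HIGH replicate 3. Control libraries 3 and 3.1 of the clawed frog lead table differed by 1.302 times the sampling noise (chi-square per degree of freedom), the lowest of all pairs of libraries within a group (the next was 2.769), and were summed and counted as 1 sample.

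Adult quail liver gave 1 identifier higher and 2 lower with lead (n = 5 and 5). This count was 0 without HIGH replicate 2 or control 1, 1 without HIGH replicate 3 or 4, and 6 without HIGH replicate 5. DESeq2 called 103, and 0 were left when only the 2 groups compared were fitted. A further quail table for lead, under the early-life name, holds 5 MED and 5 HIGH libraries and no labelled control. All 10 had the same count as the adult library of the same name for every one of 18350 identifiers, so this table is not an independent experiment. HIGH against MED in it gave 0 edgeR calls, with 810 identifiers at an unadjusted p below 0.05 and 35 DESeq2 calls.

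Ethinylestradiol mostly raised identifiers, and a few of them by large factors. In adult minnow liver 21 rose, with a median log2 fold change of 5.73, and 3 fell (n = 4 and 5). These medians are over called identifiers only. In simulated counts 5.97% of 2-fold and 60.61% of 4-fold changes were called in adult minnow. In minnow embryos it was 67.16% and 93.94%, so the adult minnow median leans more to large changes. In minnow embryos 15 rose, with a median of 3.62, and none of 16775 fell (n = 5 and 5). Early-life quail liver had 107 higher (median 1.41) and 18 lower (median -0.92), and adult quail liver 7 higher (median 2.05; n = 5 and 6). In trout embryos, with 3 libraries in each group, 160 rose (median 0.93) and 60 fell (median -0.65). In minnow and in trout embryos 2 of the identifiers that rose had a count of 0 in every control, and both medians stayed the same with these at a lower bound set by 3 counts over the control group. Leopard frog and clawed frog embryos gave 0 edgeR calls each, with 816 and 145 identifiers at an unadjusted p below 0.05, and DESeq2 also called 0 in both.

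At MED ethinylestradiol gave more calls than at HIGH in early-life quail liver, 160 in all, 119 higher (median log2 fold change 1.31) and 41 lower (median -0.70). That count was 86 without MED replicate 3, 90 without control 1 and 103 without control 5, and DESeq2 called 437. In adult minnow liver 7 rose at MED (median 7.40; 4 without control B, 11 with only the 2 groups compared and 20 with DESeq2), and in minnow embryos 6 rose (median 4.16). In trout embryos 38 rose at MED (median 1.12) and 8 fell (median -1.11). The trout count of 46 was 24 without MED replicate C, 28 without control A or B, 74 without control C, 284 without the low-count filter and 150 with DESeq2. Adult quail liver, leopard frog embryos and clawed frog embryos gave 0 edgeR calls at MED, with 957, 518 and 1535 identifiers at an unadjusted p below 0.05, and DESeq2 called 24, 0 and 4. Adult minnow liver at LOW also gave 0, with 313 at an unadjusted p below 0.05 and 1 DESeq2 call. Adult quail gave 5 calls at MED when only the 2 groups compared were fitted.

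The adult minnow and minnow embryo lists for ethinylestradiol shared 7 identifiers that rose, against 0.0204 expected (Fisher's exact test, adjusted p = 2.07e-16). Minnow and trout embryos also shared 7 (0.114 expected, adjusted p = 4.05e-11). Adult minnow shared 5 with early-life quail (0.0975 expected, adjusted p = 2.41e-07) and 5 with trout embryos (0.154 expected, adjusted p = 2.02e-06), and early-life quail shared 4 with trout embryos (0.673 expected, adjusted p = 0.0171). With only the 2 groups compared, adult minnow shared 4 with minnow embryos, 2 with early-life quail and 3 with trout. With a replicate block it shared 2, 1 and 2 in that order. The overlaps of trout with minnow embryos (6 and 9) and with early-life quail (4 and 3) stayed similar. Over all 7 ethinylestradiol experiments, 15 identifiers rose in at least 2 (1.41 from independent calls), 6 in at least 3 (0.00267) and 2 in at least 4 (2.05e-06). Identifiers called in trout embryos had the same sign for 46.1% of 204 in minnow embryos and 41.9% of 167 in adult minnow. In early-life quail it was 67.2% of 116. Those called in minnow embryos had it for 81.8% of 11 in trout embryos and 78.6% of 14 in adult minnow. Those called in early-life quail had it for 69.2% of 78 in adult minnow and 54.3% of 94 in minnow embryos. Signs thus did not agree in every pair, and these shares were not tested.

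Single libraries moved several of the counts of calls for ethinylestradiol. The adult minnow count of 24 was 430, 304, 336 and 66 without HIGH replicates B, C, E and D, and 12 and 14 without controls E and B. Without control A the minnow embryo count of 15 became 1280. The early-life quail count, 107 higher and 18 lower, became 82 without HIGH replicate 2 and 80, 79 and 75 without controls 1, 2 and 4. Adult quail gave 0 calls without control 3, 4, 5 or 6, 3 without control 2, 4 without HIGH replicate 1, 2 without HIGH replicate 2 and 15 without HIGH replicate 5. The trout count of 220 was 51 and 61 without controls A and B, and 98 and 111 without HIGH replicates B and C.

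**Figure D2:**
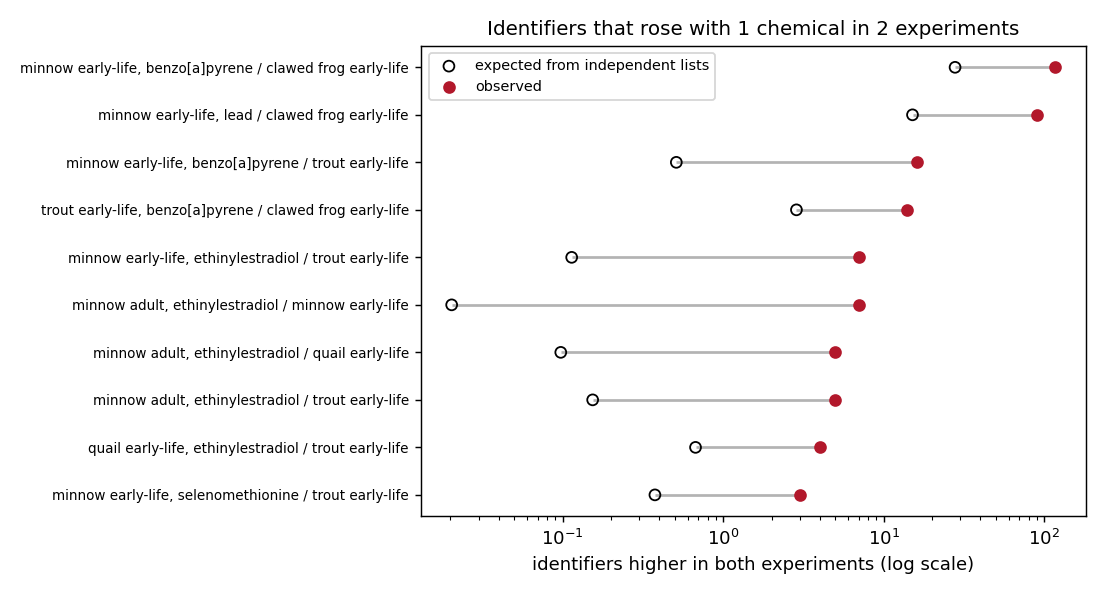
Number of identifiers that rose with the same chemical in 2 experiments (filled points), beside the number expected from independent lists (open points), on a logarithmic axis, for each pair in which both lists held at least 10 identifiers. All 10 filled points lie to the right of their open points, from 3 against 0.376 for selenomethionine in minnow and trout embryos to 117 against 27.8 for benzo[a]pyrene in minnow and clawed frog embryos.

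Whether the change with ethinylestradiol differed between adult and early-life quail liver was tested in 1 fit over both tables, with 1 estimate of the spread for both stages. The change differed for 59 of 13363 identifiers, 26 with a higher and 33 with a lower log2 fold change in adults, and for 50 of the 59 the fitted changes had opposite signs at the 2 stages. Stage and table are the same split here. A handling difference shared by all libraries of 1 table cancels in this term. One that parts HIGH from control libraries within a table would enter it. The labels do not say whether HIGH is the same dose at both stages. The count ranged from 28, without early-life control 4, to 105, without adult HIGH replicate 3. It was also below 40 without adult control 3 (37), without adult HIGH replicate 2 (36), without early-life HIGH replicates 1, 2, 3 and 5 (33, 34, 32 and 39), and without early-life controls 1 and 2 (36 and 34).

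Selenomethionine raised 95 identifiers (median log2 fold change 1.002) and lowered 23 (median -0.43) in minnow embryos (n = 4 and 4). In trout embryos 70 rose (median 0.54) and 82 fell (median -0.74; n = 4 and 5). Clawed frog embryos had 12 higher (median 1.48) and 3 lower (median -1.96; n = 5 and 5). Of the identifiers that rose, minnow and trout embryos shared 3 against 0.376 expected (Fisher's exact test, adjusted p = 0.0222), and 0 when each fit held only the 2 groups compared. Adult minnow and early-life quail liver gave 0 edgeR calls, with 394 and 747 identifiers at an unadjusted p below 0.05, and DESeq2 called 1 and 5. The minnow embryo count of 118 was 52 and 73 without HIGH replicates D and C, and 56, 40, 66 and 66 without controls A, B, C and D. In trout the count of 152 was 100 and 94 without controls C and D. The clawed frog count of 15 was 2 without HIGH replicate 2, control 2 or control 3, 4 without HIGH replicate 1 and 32 without HIGH replicate 5. With only the 2 groups compared each of these 3 counts fell by more than 1.5 times. With DESeq2 each rose by more than 1.5 times. A replicate block raised the minnow and clawed frog counts by more than 1.5 times.

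Hexabromocyclododecane changed 123 identifiers in clawed frog embryos, 68 upward (median log2 fold change 0.93) and 55 downward (median -0.77), and 50 at MED. In minnow embryos 10 rose (median 1.73) and 14 fell (median -1.08), and 26 were called at MED. Each group held 5 libraries. The clawed frog count was 186 without HIGH replicate 1, 76, 57 and 60 without HIGH replicates 2, 3 and 5, and 78, 81 and 58 without controls 2, 3 and 4. In minnow embryos the count of 24 was 39 without control A, 8 without HIGH replicate C or E, 4 without HIGH replicate A, B or D or control D or E, and 5 without control C.

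Chlorpyrifos raised 3 identifiers in early-life cormorant liver (median log2 fold change 1.16, n = 5 and 4), which became 7 without control 1 and 9 without HIGH replicate 1. In minnow, leopard frog and clawed frog embryos edgeR called 0, with 686, 2316 and 1295 identifiers at an unadjusted p below 0.05, and DESeq2 called 0, 414 and 0. The leopard frog count was 116 without control 5, the minnow count 1 without control E and the clawed frog count 2 without HIGH replicate 1. Fluoxetine gave 0 edgeR calls at the highest level in every one of 6 experiments. The identifiers at an unadjusted p below 0.05 numbered 1013 in cormorant, 1267 in adult minnow, 1102 in minnow embryos, 542 in leopard frog, 1451 in trout (n = 3 and 3) and 690 in clawed frog. DESeq2 called 14, 44, 0, 0, 58 and 1 in the same order. In trout the edgeR count was 80 without control A, 35 without replicate C of the highest level and 2 without control C, and in clawed frog it was 1 without control 4.

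Trenbolone gave 0 edgeR calls at HIGH in adult minnow liver, minnow embryos, early-life quail liver and clawed frog embryos. The identifiers at an unadjusted p below 0.05 numbered 840, 626, 624 and 1673, and DESeq2 called 0, 0, 1 and 29. In clawed frog embryos MED gave 261 calls, 26 higher and 235 lower, with a median log2 fold change of -0.65 among those lower. HIGH against MED called 0 in the same table with edgeR. At MED the count was 0 without control 3, control 5, MED replicate 2 or MED replicate 3. It was 39, 81 and 114 without control 2, control 4 and MED replicate 5, and 483 without MED replicate 1. At HIGH it was 1 without HIGH replicate 5. Other counts at MED, for which no library was left out in turn, were 8 for chlorpyrifos in cormorant liver (3 higher, 5 lower), 1 for fluoxetine in adult minnow liver and 1 in clawed frog embryos, 5 for selenomethionine in trout embryos (1 higher, 4 lower), and for benzo[a]pyrene 6 in early-life quail liver and 1 in leopard frog embryos.

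Further tables had no control library that the labels name, and there HIGH was compared with MED (5 libraries each). All 52 columns of counts without a sample in the labels lie in these 10 tables, 5 or 6 in each, and carry the letter S and a number in their names, as the titles of labelled controls do in the other cormorant and quail tables. No label gives them a treatment, and each held the same set of counts above 0 as a labelled control of another table of the same species. Whether they are those controls is stated by no label, and they were not used here, so HIGH against MED says nothing of a change from an unexposed state. In early-life quail liver chlorpyrifos at HIGH gave 63 identifiers higher (median log2 fold change 1.57) and 20 lower (median -1.21) than at MED, and the count of 83 was 45 and 50 without HIGH replicates 3 and 4 and 34, 43, 43 and 41 without MED replicates 2, 3, 4 and 5. In adult quail liver selenomethionine gave 34 higher (median 2.64) and 21 lower (median -0.94). Of those 55 calls 61.82% were higher, but with RLE size factors 4 calls were left and 0% were higher. The count was 0 without MED replicate 1 or 2 or HIGH replicate 1, 3 without MED replicate 3, 1 without MED replicate 4 or 5, 8 without HIGH replicate 2 and 168 without HIGH replicate 5. The other 7 tables of this kind, besides the quail lead table, gave 0 edgeR calls. Identifiers at an unadjusted p below 0.05 numbered 862 for cormorant ethinylestradiol, 252, 2011, 589 and 714 for adult quail chlorpyrifos, fluoxetine, hexabromocyclododecane and trenbolone, and 548 and 1179 for early-life quail fluoxetine and hexabromocyclododecane. DESeq2 called 36, then 1, 436, 4 and 19, then 13 and 60.

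A separate series of numbered levels in minnow embryos had no controls named by the labels and was compared with its own lowest level. Ethinylestradiol gave 3 identifiers higher at level 10, the highest (n = 2), than at level 1 (n = 3), with a median log2 fold change of 8.45 and a smallest adjusted p of 0.0022 by edgeR. This count was 1 without level 1 replicate a, b or c or level 10 replicate b, and 7 with DESeq2. At level 4 (n = 5), the comparison set in advance, 1 identifier was higher than at level 1, with a log2 fold change of 2.07, and DESeq2 called 6. Fluoxetine at the highest numbered level against level 0.5 (n = 3 and 3) gave 0 edgeR calls, with 811 identifiers at an unadjusted p below 0.05, and DESeq2 called 20. At the middle numbered level (n = 5) 2 identifiers were lower than at level 0.5 (median log2 fold change -1.88). This count was 0 without level 0.5 replicate 1 or 2 or middle level replicate 1, 2, 4 or 5, and DESeq2 called 3.

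The last question was whether the same identifiers were called across experiments more often than independent calls would give. Over 25478 identifiers, 16 were called in more experiments than the shares of calls in each experiment allow (one-sided Poisson-binomial test, adjusted p below 0.05). The number was 7 with only the 2 groups compared, 10 with DESeq2, 50 without the low-count filter and 29 with calls limited to an absolute log2 fold change of at least 1. All calls of 14 of the 16 were higher and 2 had calls in both directions. Of the 16, 10 were called for 2 or more chemicals and 14 in 2 or more species.

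The identifier s2f_0000034018 rose in 6 of 38 experiments (adjusted p = 0.000199 over all identifiers). In clawed frog embryos its normalised count rose with lead from 18.5 ± 5.23 to 124.8 ± 24.9 CPM (mean ± SD, n = 5 and 5), a log2 fold change of 2.73 ± 0.191 (SE, adjusted p = 7.95e-08). The log2 fold change was 1.25 ± 0.193 with benzo[a]pyrene in clawed frog embryos (adjusted p = 0.000148), 1.41 ± 0.18 with lead (adjusted p = 0.000206) and 0.98 ± 0.178 with benzo[a]pyrene (adjusted p = 0.00552) in minnow embryos. In trout embryos it was 0.84 ± 0.18 with selenomethionine (adjusted p = 0.0237) and 0.54 ± 0.113 with benzo[a]pyrene (adjusted p = 0.0252). In each of these 6 experiments every exposed library lay above every control, but they were picked by the call, so this adds little. With selenomethionine in minnow embryos every exposed library lay below every control, without a call (-0.27, edgeR adjusted p = 0.216). With ethinylestradiol in trout embryos every exposed library lay above, also without a call (0.53, edgeR adjusted p = 0.172). Both trout calls were lost when some single libraries were left out, 4 of 9 with selenomethionine and 6 of 11 with benzo[a]pyrene. With selenomethionine the value without HIGH replicate B was 0.55.

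The identifier s2f_0004340001 also rose in 6 experiments, of 39 (adjusted p = 0.000199). With lead it rose in clawed frog embryos from 32.4 ± 2.08 to 88.4 ± 7.33 CPM (n = 5 and 5), a log2 fold change of 1.45 ± 0.0684 (SE, adjusted p = 2.15e-09), and in minnow embryos by 1.32 ± 0.162 (adjusted p = 0.000171). With benzo[a]pyrene the log2 fold change was 1.36 ± 0.164 in clawed frog embryos (adjusted p = 1.36e-05) and 0.85 ± 0.18 in minnow embryos (adjusted p = 0.0182). In trout embryos it was 0.73 ± 0.111 with ethinylestradiol (adjusted p = 0.00282) and 0.34 ± 0.0754 with selenomethionine (adjusted p = 0.0283). Every exposed library lay above every control in these 6 experiments, which were picked by the call. Leaving out single libraries ended the call for 3 of 10 with benzo[a]pyrene in minnow (controls A, C and E) and for 5 of 9 with selenomethionine in trout.

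No identifier passed the recurrence test through lower calls alone. The identifiers called lower most often were s2f_0003880003, in 3 of 35 experiments (adjusted p = 0.549), and s2f_0000716004, in 3 of 39 (adjusted p = 0.549). With lead, s2f_0003880003 had a log2 fold change of -1.11 ± 0.221 in clawed frog embryos (SE, adjusted p = 0.0105) and -0.42 ± 0.133 in minnow embryos (adjusted p = 0.0475), and with benzo[a]pyrene -0.69 ± 0.215 in clawed frog embryos (adjusted p = 0.0305). For s2f_0000716004 it was -0.95 ± 0.168 with lead in minnow embryos (adjusted p = 0.00192), -0.75 ± 0.18 with benzo[a]pyrene in minnow embryos (adjusted p = 0.0476) and -0.48 ± 0.121 with benzo[a]pyrene in clawed frog embryos (adjusted p = 0.00829). The minnow lead call of s2f_0003880003 was lost without any 1 of 8 of 10 libraries and its clawed frog benzo[a]pyrene call without any 1 of 5 of 10. The minnow benzo[a]pyrene call of s2f_0000716004 was lost without any 1 of 6 of 10.

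**Figure D3:**
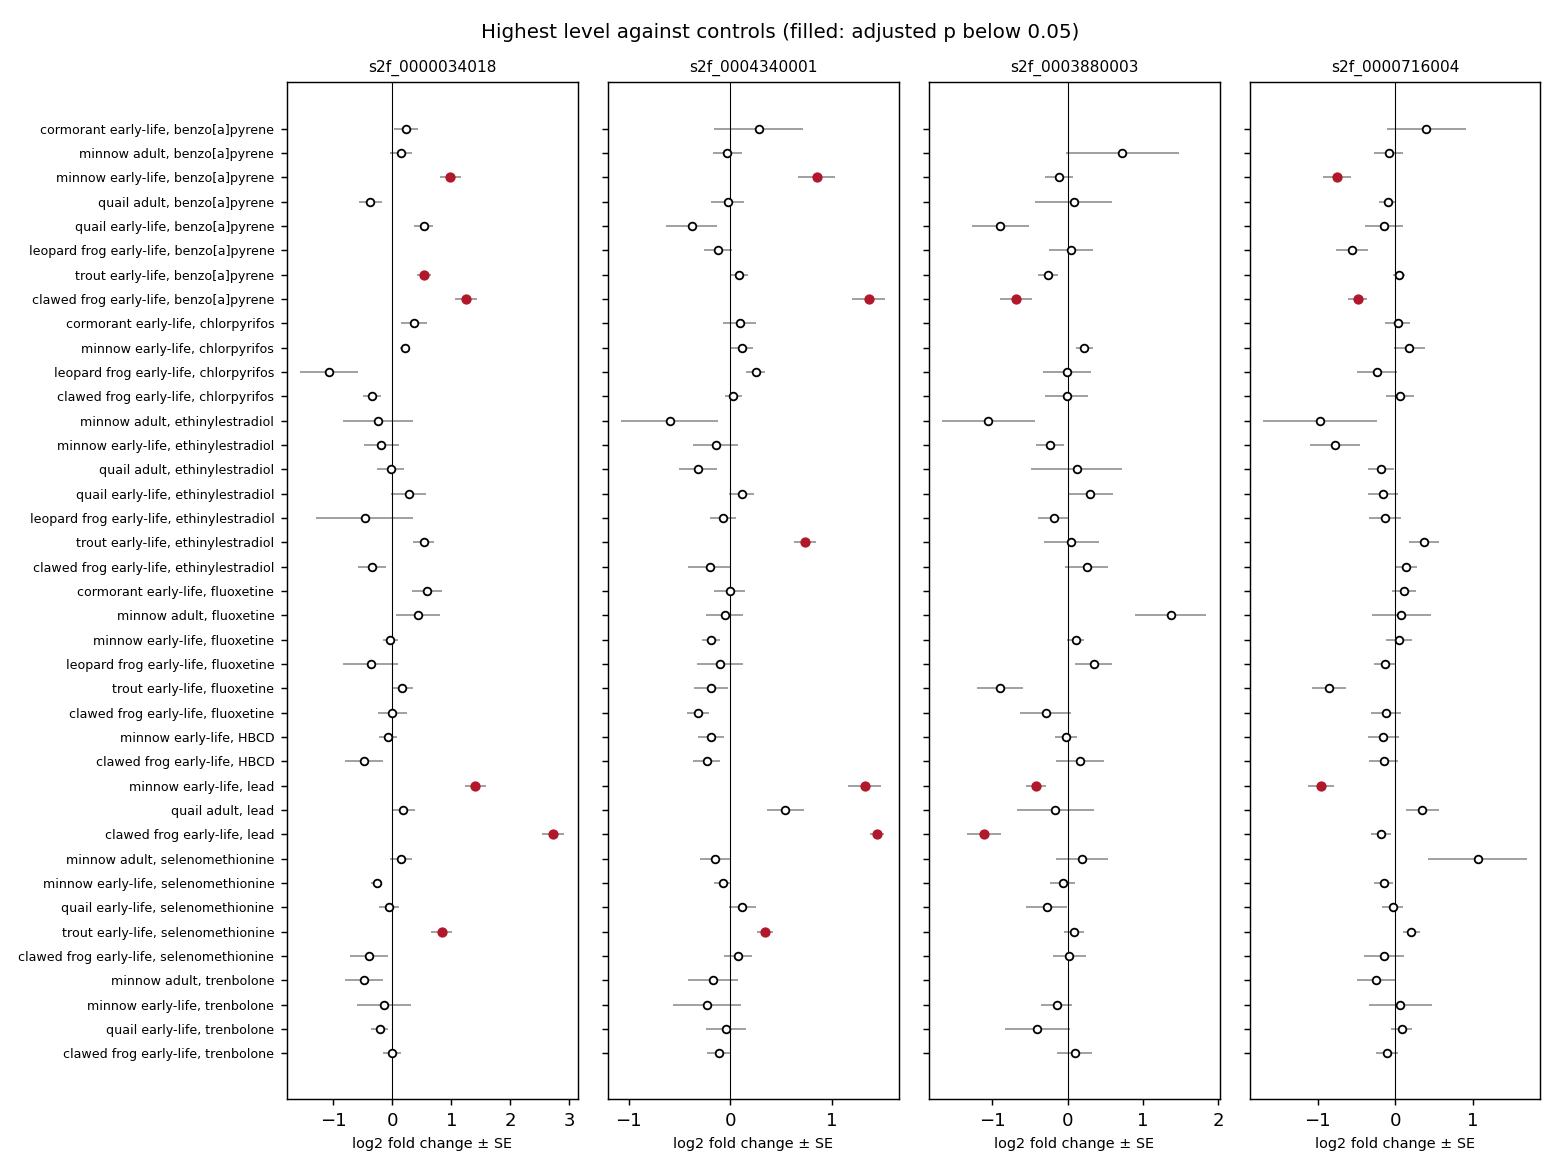
Log2 fold change ± SE of the 4 named identifiers at the highest level against controls, with 1 point per experiment in which the identifier was tested; filled red points have an adjusted p below 0.05. The filled points of s2f_0000034018 and s2f_0004340001 lie to the right of 0 in 6 experiments each and those of s2f_0003880003 and s2f_0000716004 to the left in 3 each.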

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

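The tests of the quail lead libraries, and the counts without single libraries for trenbolone at MED, were chosen only after the result was seen.

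A test of whether 2 stages respond differently gave 1 result for a closer look: the change with ethinylestradiol differed between adult and early-life quail liver for 59 identifiers. Stage and table are the same split, so handling that parts HIGH from control libraries within 1 table stays open beside the stage. The dose at HIGH, which the labels do not give, stays open too. In that fit 186 identifiers were called in adults and 74 at the early stage, and 34 and 20 of the 59 were among them. These counts rest on 1 estimate of the spread for both stages, and whether the stages differ in spread was not tested. Fitted per table, the order was the other way, with 7 calls in adults and 107 higher and 18 lower at the early stage, so the counts do not say which stage responded more. Of 40 splits of the libraries, only the real one gave as many, and the highest other gave 4. These splits mixed HIGH and control libraries within each stage, which takes away any change at either stage. They show what no change at all would give, not what the same change at both stages would give. They therefore do not exclude chance for the stage difference.

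Library totals stood apart from the rest of their group in 15 of 139 groups. The limit used is one that chance passes in about 1 group in 20 for normally distributed values, and the rate for library totals was not simulated. The highest in its group was the total of minnow adult fluoxetine control A (24316400, others at most 17553655), adult minnow trenbolone MED D (36868585, others at most 19079173), minnow embryo benzo[a]pyrene HIGH C (21223644, others at most 15736137) and MED B (18114912, others at most 15132589), and minnow embryo selenomethionine MED D (19068289, others at most 17557383). The same held for adult quail chlorpyrifos HIGH 2 (26064602, others at most 15350772), fluoxetine MED 4 (49078234, others at most 19890212), and hexabromocyclododecane MED 2 (24722100, others at most 16401221) and HIGH 3 (38420774, others at most 18766022). In frogs it held for leopard frog fluoxetine HIGH 2 (13531636, others at most 8976195) and for clawed frog benzo[a]pyrene HIGH 2 (33761151, others at most 14529106), lead MED 4 (17859176, others at most 11246340) and trenbolone HIGH 3 (27007039, others at most 15152928). The lowest in their groups were minnow embryo trenbolone MED A (9224261, others at least 13630301) and clawed frog fluoxetine MED 3 (13737220, others at least 16735865). Among the named identifiers, 1 of 34 groups held a value apart: s2f_0000716004 was at 96.66 CPM in minnow embryo benzo[a]pyrene HIGH A, where the other 4 libraries lay between 67.71 and 76.04.

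Lead in quail was deposited under both stages with the same counts. By Pearson correlation across identifiers of log2 CPM, which are not independent replicates, all 10 libraries were closer to adult quail liver libraries of other tables than to early-life ones, and 0 the other way. Their lowest median correlation with the 81 adult libraries was 0.9528 and their highest with the 90 early-life libraries 0.9049, over 16110 identifiers, where the median was 0.9772 within adults, 0.9832 within the early stage and 0.8942 between them. This is consistent with libraries from adult quail under both names and argues against early-life quail as their source. A biological difference between the tables is not at issue, since the counts are identical.

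Trenbolone in clawed frog embryos gave 261 edgeR calls at MED and 0 at HIGH, where 1673 identifiers had an unadjusted p below 0.05 and DESeq2 called 29. Thinning all libraries to the lowest total (8545252) left 204 calls, of which 183 were among the 261, which argues against library totals as the cause. Without control 3 the MED count was 0, and likewise without control 5 or MED replicate 2 or 3, so single libraries decide whether the count is large. A change of the same kind at HIGH that missed the threshold may also account for the pattern, since 0 of the identifiers called at MED differed between HIGH and MED, a test that leaves out the controls. A missed threshold does not show that both levels acted alike, and how the dose acts stays open.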

How the results depend on the processing

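The fits for overlaps, for recurrence (except the limit on fold change), for each lower level, for the other numbered levels in minnow embryos and with both clawed frog lead controls numbered 3 were chosen only after results were seen. Counts of calls are called similar when they lie within 1.5 times the reported count, which stands in parentheses below. None of the log2 fold changes of the 18 calls of named identifiers changed sign under the alternatives tried. These values were picked by the call, so a change of sign was unlikely from the start. Values of the named identifiers without a call were not followed. Counts have no sign, but the share of higher calls for selenomethionine in adult quail (HIGH against MED) went from 61.82% of 55 to 0% of 4 with RLE factors. Of 62 counts 61 were similar with RLE size factors, 55 without the low-count filter and 13 with DESeq2, where 48 were higher and 1 was lower. With only the 2 groups compared 36 of 50 were similar, and with a replicate block 41 of 59. Of 534 counts without 1 library 423 were similar, 79 lower and 32 higher. A count of 0 that stayed 0 is among the similar ones, here and for the alternatives above. Many comparisons had a count of 0, so these shares overstate how stable the counts above 0 were to leaving out 1 library. The fold changes of the 18 calls of named identifiers all stayed past the threshold with RLE factors and DESeq2, 17 without the filter and with the block, and 11 with only the 2 groups compared. Of 175 such values without 1 library 138 stayed past it. Of 28 overlaps 28 were similar with RLE factors, 24 without the filter, 15 with DESeq2, 14 with the block and 7 with only the 2 groups compared. The clawed frog lead count of 282 was 354 with controls 3 and 3.1 counted separately and 276 without 3.1. Gene set tests and their preset correlation were not run, since no identifier had a name. A fit of the 2 groups alone has fewer libraries from which to estimate the spread; for all other changes the cause was not tested. Where simulated 2-fold changes were seldom recovered, as in adult minnow (median 23.88%), a count of 0 limits only larger changes.

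Recurrence over experiments passed for 16 identifiers, and for 10 with DESeq2, 7 with only the 2 groups compared, 50 without the low-count filter, and 29 with calls limited to an absolute log2 fold change of at least 1, of which 10 were among the 16. Benzo[a]pyrene in trout gave 28 (46) with only the 4 controls whose titles start with S. RLE size factors moved 1 count past 1.5 times, selenomethionine 4 (55) for adult quail (HIGH against MED). Without the low-count filter selenomethionine counts were 108 (55) for adult quail (HIGH against MED). Without the low-count filter ethinylestradiol counts were 707 (220) for trout and 458 (170 higher, 49 lower) for the lower levels. Without the low-count filter fluoxetine counts were 98 (0) for trout, 1 (0) for minnow embryos (highest numbered level against 0.5) and 8 (2) for the lower levels.

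Benzo[a]pyrene counts with DESeq2 were 206 (0) for cormorant, 478 (282) for minnow embryos, 1 (0) for adult quail, 111 (3) for early-life quail, 13 (6) for leopard frog, 995 (528) for the lower levels and 29 (0) for the quail stage difference. Chlorpyrifos counts with DESeq2 were 57 (3) for cormorant, 1 (0) for adult quail (HIGH against MED), 427 (83) for early-life quail (HIGH against MED), 414 (0) for leopard frog and 61 (8) for the lower levels. Ethinylestradiol counts with DESeq2 were 36 (0) for cormorant (HIGH against MED), 248 (24) for adult minnow, 35 (15) for minnow embryos, 108 (7) for adult quail, 289 (107 higher, 18 lower) for early-life quail, 6 (1) for minnow embryos (level 4 against 1), 644 (170 higher, 49 lower) for the lower levels, 195 (59) for the quail stage difference, 8 (5) for the overlap of adult minnow and early-life quail and 9 (4) for the overlap of early-life quail and trout. Fluoxetine counts with DESeq2 were 14 (0) for cormorant, 44 (0) for adult minnow, 436 (0) for adult quail (HIGH against MED), 13 (0) for early-life quail (HIGH against MED), 58 (0) for trout, 1 (0) for clawed frog, 20 (0) for minnow embryos (highest numbered level against 0.5) and 176 (2) for the lower levels. Selenomethionine counts with DESeq2 were 1 (0) for adult minnow, 267 (118) for minnow embryos, 564 (55) for adult quail (HIGH against MED), 5 (0) for early-life quail, 261 (152) for trout, 103 (15) for clawed frog, 39 (5) for the lower levels and 9 (3) for the overlap of minnow embryos and trout. Hexabromocyclododecane counts with DESeq2 were 96 (24) for minnow embryos, 4 (0) for adult quail (HIGH against MED), 60 (0) for early-life quail (HIGH against MED), 365 (123) for clawed frog and 321 (76) for the lower levels. Lead counts with DESeq2 were 103 (3) for adult quail, 35 (0) for the copies of adult quail libraries under the early-life name (HIGH against MED), 464 (282) for clawed frog and 591 (331) for the lower levels. Trenbolone counts with DESeq2 were 19 (0) for adult quail (HIGH against MED), 1 (0) for early-life quail, 29 (0) for clawed frog and 896 (261) for the lower levels.

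Ethinylestradiol counts with only the 2 groups compared were 9 (24) for adult minnow, 4 (7) for adult quail, 4 (7) for the overlap of adult minnow and minnow embryos, 2 (5) for the overlap of adult minnow and early-life quail and 3 (5) for the overlap of adult minnow and trout. Selenomethionine counts with only the 2 groups compared were 37 (118) for minnow embryos, 73 (152) for trout, 8 (15) for clawed frog, 9 (5) for the lower levels and 0 (3) for the overlap of minnow embryos and trout. Benzo[a]pyrene counts with only the 2 groups compared were 126 (282) for minnow embryos, 1 (3) for early-life quail, 814 (528) for the lower levels, 67 (117) for the overlap of minnow embryos and clawed frog, 9 (16) for the overlap of minnow embryos and trout and 9 (14) for the overlap of trout and clawed frog. Lead counts with only the 2 groups compared were 0 (3) for adult quail. Fluoxetine counts with only the 2 groups compared were 5 (2) for the lower levels. Trenbolone counts with only the 2 groups compared were 706 (261) for the lower levels. Hexabromocyclododecane counts with only the 2 groups compared were 30 (76) for the lower levels.

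Replicate letters paired the libraries in 4 minnow embryo comparisons. There the block changed lead as given below, and ethinylestradiol had 21 (15), chlorpyrifos 0 (0) and fluoxetine 0 (0), so it changed no other call by over 1.5 times. In the other comparisons not every pair was over 0.1, but libraries with the same number or letter could still resemble each other. Their mean correlation ran from -0.262 (fluoxetine in trout) to 0.309 (trenbolone in minnow embryos). It was 0.135 for selenomethionine in minnow embryos. In clawed frog it was 0.205 for lead, 0.207 for selenomethionine and 0.185 for hexabromocyclododecane. A pairing is not excluded there. Fluoxetine counts with a replicate block were 1 (0) for cormorant and 5 (2) for the lower levels. Ethinylestradiol counts with a replicate block were 4 (24) for adult minnow, 0 (7) for adult quail, 80 (107 higher, 18 lower) for early-life quail, 2 (7) for the overlap of adult minnow and minnow embryos, 1 (5) for the overlap of adult minnow and early-life quail and 2 (5) for the overlap of adult minnow and trout. Hexabromocyclododecane counts with a replicate block were 4 (24) for minnow embryos, 2 (0) for early-life quail (HIGH against MED), 477 (123) for clawed frog and 240 (76) for the lower levels. Lead counts with a replicate block were 3854 (2203) for minnow embryos, 0 (3) for adult quail, 467 (282) for clawed frog, 571 (331) for the lower levels and 139 (90) for the overlap of minnow embryos and clawed frog. Selenomethionine counts with a replicate block were 517 (118) for minnow embryos, 0 (55) for adult quail (HIGH against MED), 87 (15) for clawed frog and 7 (3) for the overlap of minnow embryos and trout. Chlorpyrifos counts with a replicate block were 23 (83) for early-life quail (HIGH against MED). Trenbolone counts with a replicate block were 158 (261) for the lower levels. Benzo[a]pyrene counts with a replicate block were 9 (16) for the overlap of minnow embryos and trout.

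Leave-one-out chlorpyrifos counts were 2 to 9 (3) for cormorant, 0 to 1 (0) for minnow embryos, 34 to 114 (83) for early-life quail (HIGH against MED), 0 to 116 (0) for leopard frog and 0 to 2 (0) for clawed frog. Leave-one-out benzo[a]pyrene counts were 0 to 1 (0) for adult minnow, 200 to 443 (282) for minnow embryos, 1 to 3 (3) for early-life quail, 3 to 6 (6) for leopard frog and 29 to 50 (46) for trout. Leave-one-out ethinylestradiol counts were 12 to 430 (24) for adult minnow, 12 to 1280 (15) for minnow embryos, 0 to 15 (7) for adult quail, 75 to 163 (107 higher, 18 lower) for early-life quail, 51 to 281 (220) for trout and 28 to 105 (59) for the quail stage difference. Leave-one-out hexabromocyclododecane counts were 4 to 39 (24) for minnow embryos, 0 to 3 (0) for early-life quail (HIGH against MED) and 57 to 186 (123) for clawed frog. Leave-one-out selenomethionine counts were 40 to 129 (118) for minnow embryos, 0 to 168 (55) for adult quail (HIGH against MED), 94 to 189 (152) for trout and 2 to 32 (15) for clawed frog. Leave-one-out fluoxetine counts were 0 to 1 (0) for adult quail (HIGH against MED), 0 to 80 (0) for trout, 0 to 1 (0) for clawed frog and 0 to 1 (0) for minnow embryos (highest numbered level against 0.5). Leave-one-out lead counts were 0 to 6 (3) for adult quail, 0 to 1 (0) for the copies under the early-life name (HIGH against MED) and 184 to 320 (282) for clawed frog. Leave-one-out trenbolone counts were 0 to 1 (0) for adult quail (HIGH against MED) and 0 to 1 (0) for clawed frog.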

Other observations

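The overlap of benzo[a]pyrene with lead was singled out after the overlaps had been seen, and the alternatives of the overlaps were added then; the tests of its explanations and the splits were set before their results.

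Identifiers that rose with benzo[a]pyrene overlapped those that rose with lead: 109 against 27.1 expected within clawed frog embryos, 71 against 18 within minnow embryos, 35 against 3.75 for benzo[a]pyrene in minnow and lead in clawed frog, 185 against 113 the other way round, and for benzo[a]pyrene in trout 13 against 2.23 with lead in minnow and 5 against 0.391 with lead in clawed frog. The one-sided Fisher's exact test gave an adjusted p of at most 0.000175 for these 6 overlaps, where 23 of 92 tests between chemicals passed the threshold. Within deciles of abundance at least 94.5% of the excess was left, which argues against abundance as the whole cause. With RLE factors at least 84.2% was left. These factors hardly differ from TMM here: the largest shift of the median log2 fold change was -0.0107, for benzo[a]pyrene in minnow embryos. The swap therefore cannot decide whether scaling is a cause. The sizes depend on the fit: with only the 2 groups compared the overlaps were 95, 33, 10, 8 and 3, and with DESeq2 162, 118, 62, 17 and 11, in the order above without the overlap of 185, which was higher in both. The excess was not particular to this pair: lead and selenomethionine shared 26 against 6.16 in minnow embryos (4.22 times the expected number, beside 3.94 for lead and benzo[a]pyrene there), and ethinylestradiol in trout and lead in clawed frog 10 against 1.8. Of the identifiers that fell, benzo[a]pyrene and lead shared 11 against 3.57 in clawed frog (Fisher's exact test, adjusted p = 0.0023). In minnow embryos they shared 4 against 0.786 (same test, adjusted p = 0.0222). For lead in minnow and benzo[a]pyrene in clawed frog it was 44 against 58.7. Within trout embryos ethinylestradiol shared 4 falls with benzo[a]pyrene against 0.0417 (same test, adjusted p = 4.91e-07). With selenomethionine it shared 5 against 0.302 (same test, adjusted p = 7.02e-05). Lead in minnow and ethinylestradiol in trout shared 0 falls against 3.91. What the shared identifiers have in common was not tested, and batches are not named in the labels.

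Recurrence over experiments was concentrated in few identifiers: 40 were called in at least 4 experiments, where independent calls give 1.173, and 8 in at least 5, where they give 0.02331. Spearman correlations of log2 fold changes across identifiers, which are not independent replicates, had a mean of 0.0145 over 90 pairs of experiments with the same chemical (from -0.2419 to 0.2602), 0.0571 over 90 pairs with the same species and stage (from -0.4543 to 0.4614), and 0.0025 over 561 pairs with neither (from -0.244 to 0.2909). The means lie near 0 over pairs that go both ways: in minnow embryos ethinylestradiol had -0.4543 with chlorpyrifos and 0.4417 with fluoxetine.

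Other splits of the same libraries into groups of the same sizes were fitted in the same way, 40 for each comparison with the real one, or 35 where no more exist. For 19 comparisons only the real split gave as many calls (1 split), a share under 5% for each taken alone. These shares were not adjusted for the number of comparisons, so some of the 19 may still be due to chance. The real count and the highest of the other splits were 24 against 5 for ethinylestradiol in adult minnow, 24 against 0 for hexabromocyclododecane in minnow embryos, 2203 against 0 for lead in minnow embryos, 118 against 1 for selenomethionine in minnow embryos, 282 against 0 for benzo[a]pyrene in minnow embryos, 55 against 2 for selenomethionine in adult quail (HIGH against MED) and 3 against 1 for benzo[a]pyrene in early-life quail. They were 83 against 1 for chlorpyrifos in early-life quail (HIGH against MED), 107 higher and 18 lower against 2 for ethinylestradiol in early-life quail, 152 against 120 for selenomethionine in trout, 46 against 8 for benzo[a]pyrene in trout, 3169 against 4 for benzo[a]pyrene in clawed frog, 123 against 4 for hexabromocyclododecane in clawed frog and 15 against 2 for selenomethionine in clawed frog. Further pairs were 282 against 2 for lead in clawed frog. At summed lower levels they were 528 against 198 for benzo[a]pyrene, 76 against 50 for hexabromocyclododecane and 331 against 286 for lead. The quail stage difference of ethinylestradiol had 59 against 4, by splits that also took away the change at each stage.

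For 11 comparisons with calls 5% or more of the splits gave as many, so there chance is not excluded even for 1 comparison taken alone. The real counts were 3 for chlorpyrifos in cormorant (2 of 40 splits as large, highest other 7), 15 for ethinylestradiol in minnow embryos (3 of 40 splits as large, highest other 4049; among splits that part every letter pair the highest other was 0), 7 for ethinylestradiol in adult quail (2 of 40 splits as large, highest other 11) and 3 for lead in adult quail (2 of 40 splits as large, highest other 14). Others were 6 for benzo[a]pyrene in leopard frog (2 of 40 splits as large, highest other 6), 1 for ethinylestradiol in minnow embryos (level 4 against 1) (3 of 40 splits as large, highest other 303), 8 for chlorpyrifos at summed lower levels (4 of 40 splits as large, highest other 821) and 2 for fluoxetine at summed lower levels (8 of 40 splits as large, highest other 1251). There were also 261 for trenbolone at summed lower levels (2 of 40 splits as large, highest other 261), 170 higher and 49 lower for ethinylestradiol at summed lower levels (3 of 40 splits as large, highest other 3031) and 5 for selenomethionine at summed lower levels (2 of 40 splits as large, highest other 5). At summed lower levels the splits were drawn without a check for repeats. The other 261 for trenbolone may thus be the real grouping drawn again, which leaves that share undecided. These splits also ignored the letter pairs of the minnow embryo tables. Where the real count was 0 all 40 splits are as large by construction, so there the splits say nothing of chance. The highest other count was then 0 for benzo[a]pyrene in cormorant, 3168 for ethinylestradiol in cormorant (HIGH against MED), 3 for fluoxetine in cormorant, 5 for benzo[a]pyrene in adult minnow, 2 for fluoxetine in adult minnow, 2 for trenbolone in adult minnow, 0 for selenomethionine in adult minnow, 1 for fluoxetine in minnow embryos, 0 for trenbolone in minnow embryos and 1366 for chlorpyrifos in minnow embryos. It was 1 for benzo[a]pyrene in adult quail, 11 for chlorpyrifos in adult quail (HIGH against MED), 1 for fluoxetine in adult quail (HIGH against MED), 1 for hexabromocyclododecane in adult quail (HIGH against MED), 1 for trenbolone in adult quail (HIGH against MED), 2 for fluoxetine in early-life quail (HIGH against MED), 126 for hexabromocyclododecane in early-life quail (HIGH against MED), 2 for the copies of adult quail lead libraries under the early-life name (HIGH against MED), 1 for selenomethionine in early-life quail and 1 for trenbolone in early-life quail. Lastly it was 1 for chlorpyrifos in leopard frog, 1 for ethinylestradiol in leopard frog, 111 for fluoxetine in leopard frog, 416 for chlorpyrifos in clawed frog, 0 for ethinylestradiol in clawed frog, 1 for fluoxetine in clawed frog, 1 for trenbolone in clawed frog and 2 for quail stage difference of benzo[a]pyrene.

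With 3 libraries in each group the 10 splits are too few for a share under 0.05. The real count was 220 and the highest other 4 for ethinylestradiol in trout (1 of 10 splits as large). The real count was 0 and the highest other 385 for fluoxetine in trout (10 of 10 splits as large). The real count was 0 and the highest other 0 for fluoxetine in minnow embryos (highest numbered level against 0.5) (10 of 10 splits as large).

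In minnow embryos the letters pair the libraries for 4 comparisons, and there the 16 splits that part every pair were also fitted. Only the real split gave as many calls for ethinylestradiol (15, highest other 0) and for lead (2203, highest other 0), and for chlorpyrifos and fluoxetine all 16 splits gave 0. The splits with many calls for ethinylestradiol (up to 4049) and chlorpyrifos (up to 1366) thus keep some pairs together. Most possible splits do so whatever the letters stand for, so these counts cannot decide whether the letters carry a structure of the samples. Single splits also gave many calls where the real count was 0: 3168 for ethinylestradiol in cormorant, 385 and 111 for fluoxetine in trout and leopard frog, 416 for chlorpyrifos in clawed frog and 126 for hexabromocyclododecane in early-life quail. The median of the other splits was 0 in each, and whether these samples share a structure was not tested.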
